A study of Mus musculus with 9 samples.

How the data were processed

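CD11b+Gr1+ cells, the surface phenotype shared by neutrophils, inflammatory monocytes and their immature precursors, were sorted by flow cytometry from mouse spleens into lysis reagent, per the labels' protocols. Total RNA was extracted and amplified, and the biotin-labelled cDNA was hybridised to Affymetrix expression arrays. The 9 samples comprised 6 from single tumour-bearing L2-Cre;p120f/f mice and 3 control pools, each of which combined cells of 3 heterozygous animals (L2-Cre;p120+/f) without disease. L2-Cre drives recombination in squamous epithelium of the mouth and oesophagus, and p120 is the catenin encoded by Ctnnd1. Groups and replicate numbers came from the sample titles and source names. Other label fields of the same samples, which describe an embryonic age, a limb tissue and other genotypes, contradict the titles and were not used.

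The deposited values are log2 expression values, 1 per array row and sample, which the authors normalized across arrays. The submitters' processing notes name Affymetrix Power Tools, RMA, PLIER and the mouse build mm9. Their versions, and which method made the final values, are not given in the sources used here. The scale was read as log2 from the values, which range from 1.95 to 13.95. Array medians lay between 5.92 and 5.99. The authors' deposited table of significant changes lists 964 rows with an accession, a symbol, the log2 values of the 9 samples and a difference. That difference column is headed as a ratio, but it equals the mean of the tumour-bearing samples minus the mean of the controls on the log2 scale to within 5e-06. Its smallest absolute value is 1.0003. Per the series design, the authors selected rows with a two-sample test, permutations, a p threshold of 0.001 and a minimum change of 2-fold. Arrays give no count of molecules, and the number of arrays limits the precision.

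The value table holds 31648 rows under array identifiers without gene names. Each of the 964 rows of the authors' table matched exactly 1 row of the value table on all 9 values to 5 decimals, and these rows took their names from it. The other 30684 rows were tested and counted but are unnamed here. Every named gene had therefore already been selected by the authors on these same samples, so counts of named genes in a group are not independent evidence of its direction. Names were updated through the RefSeq annotation of GRCm38.p6, which is not the authors' build, so no coordinates are given. Of the 964 rows, 717 matched by accession, 114 by current symbol and 52 by synonym, and 81 kept the name in the file. This renamed 149 rows. The rows stand for 895 distinct gene names. For the 47 genes with more than 1 row the row of highest mean was used, and none of them had rows in both directions. Another 47 rows of the value table hold values identical to another row.

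All rows were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, tumour-bearing minus control), with Benjamini-Hochberg adjustment over 31648 rows and a threshold of 0.05. Differences are given with the standard error of that fit. The gene lists, 35 in all with 719 genes, were fixed before the data were examined, together with the tests, the alternatives and the rule for naming genes. Of their genes, 150 have a named row. List members without a named row were not analysed here, among them Ctnnd1, Itgam, Arg1, Cybb, S100a8 and S100a9, nor were Ly6g and Ly6c1, which the naming rule also held. At the authors' thresholds limma passed only 69 rows outside their table. Most list members without a named row therefore did not reach these thresholds, or have no row on the array. Lists with at least 3 named genes, 16 in number, were tested with camera at a preset inter-gene correlation of 0.01. The planned background was all measured genes, and because only the authors' rows have names, camera compared each list with the other named genes. A list can pass this test only by leaning further to one side than the authors' other genes.

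The text names the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold with complete separation of the groups, up to 4 genes of each list by absolute difference, and Nos2 among markers fixed in advance. Unnamed clones and predicted genes are left out of the first part. Genes outside this rule are said to have been chosen after their values were seen. Alternatives were median centring, quantile normalization, a filter on dim rows, means over the rows of a gene, named rows only, the methods' t-test, a Welch test, a trended robust fit, array weights, the replicate number as a block, leaving out each sample, a pseudocount of 16, camera with an estimated correlation and fry. For the plain, Welch and trended tests the lists were tested with cameraPR on the z-transformed statistics. A direction test of each list (Fisher's exact test) and limma at the authors' thresholds were added after seeing the data. The fit was tested on simulated values for the same 31648 rows. With 200 rows changed, 82% of those changed by 2-fold and 100% of those changed by 4-fold were recovered, with 6 calls among unchanged rows. With no change at all there were 0 calls. The simulated noise was normal, independent between rows and of the same spread in both groups. These rates therefore need not hold for correlated genes, unequal spreads or as many changed rows as in the data. Python 3.11.15 with scipy 1.17.1 and numpy 2.4.6 was used for the permutation tests.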

Results

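Expression arrays were compared between CD11b+Gr1+ spleen cells of 6 tumour-bearing L2-Cre;p120f/f mice and 3 pools of such cells from healthy controls, to find the transcripts that distinguish these myeloid cells in mice with tumours. Values are log2 expression, and differences are tumour-bearing minus control. Correlations between arrays over all rows were 0.985 to 0.991 within the tumour-bearing group, 0.986 to 0.990 within the controls and 0.954 to 0.974 across groups. The first principal component held 56.2% of the variance and separated the groups. The median standard deviation of a row was 0.107 among single mice and 0.100 among pools. Tumour, genotype and pooling all coincide with group and cannot be told apart. The labels record no batch, so whether a batch also follows group is not known.

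Among the named genes, those of the primary granules of neutrophil precursors had some of the highest rises in the tumour-bearing mice. Ctsg (cathepsin G) rose by 4.42 ± 0.22 (SE) on the log2 scale, 21.3-fold, from 6.95 ± 0.05 (SD, n = 3 pools) to 11.36 ± 0.40 (SD, n = 6 mice). Mpo (myeloperoxidase) rose 16.3-fold, Prtn3 (proteinase 3) 14.1-fold and Elane (neutrophil elastase) 9.53-fold. Among the largest falls were Ptgs2 (cyclooxygenase-2), 16.9-fold lower at -4.07 ± 0.17 (SE), and the MHC class II genes H2-Aa, 11.6-fold lower, and H2-Ab1, 8.97-fold lower. Of all 31648 rows, 7333 changed (limma, Benjamini-Hochberg), 4538 higher and 2795 lower in the tumour-bearing mice. Of these, 561 were higher and 560 lower by at least 2-fold. After quantile normalization the split was 4014 higher and 3570 lower (52.9% higher, against 61.9% as deposited), and 509 higher and 622 lower by at least 2-fold. With a separate variance for each group 3800 rows passed.

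The other named genes with the highest rises were H3c8 (a histone H3 gene, 4.29 ± 0.52 SE), Cd38 (an NAD-hydrolysing ectoenzyme, 3.87 ± 0.22), Ms4a3 (a marker of granulocyte-monocyte progenitors, 3.43 ± 0.19), Prok2 (prokineticin 2, 3.02 ± 0.19), Plk4 (a kinase of centriole duplication, 2.94 ± 0.28) and Cip2a (an inhibitor of the phosphatase PP2A, 2.61 ± 0.13). The falls were led by the bitter taste receptor genes Tas2r135 (-4.46 ± 0.32 SE) and Tas2r143 (-4.30 ± 0.34). Bcl2a1d, a survival gene of the Bcl2 family, followed at -3.49 ± 0.32. Cd101, an inhibitory receptor of mature neutrophils, stood at -3.32 ± 0.24, the C-type lectin gene Clec4n at -3.26 ± 0.12, the invariant chain gene Cd74 at -3.21 ± 0.25 and the proteasome gene Psma3 at -3.17 ± 0.27. The limma adjusted p of these 20 genes lay between 8.774e-06 and 0.0004766, and for each of them all 6 mice lay on the same side of all 3 pools. H3c8 and Bcl2a1d have near-identical copies in the genome, so their rows are uncertain as to the gene. Psma3 rests on a single accession that is not a RefSeq transcript, so its row is also uncertain as to the gene. The rows of Ms4a2 and Tnfrsf10b, named below, also carry such an accession and share this doubt. The lower group means of H3c8 (4.13 in controls), Bcl2a1d (4.52 in tumour-bearing mice) and Psma3 (4.07 in tumour-bearing mice) lie near the low end of the scale. With these, 11 of the 80 genes that the naming rule gave, among them Ptgs2 (5.81 in tumour-bearing mice), Plk4, Ifi44, Gbp5, Il18, Nos2, Nqo1 and Ms4a2, had a group mean below every array median. No background call was made, so the size and rank of their changes are uncertain. Plk4 has another row, with a smaller rise of 1.94 ± 0.10. Elane and Plk4 did not pass with a separate variance for each group.

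**Figure D1:**
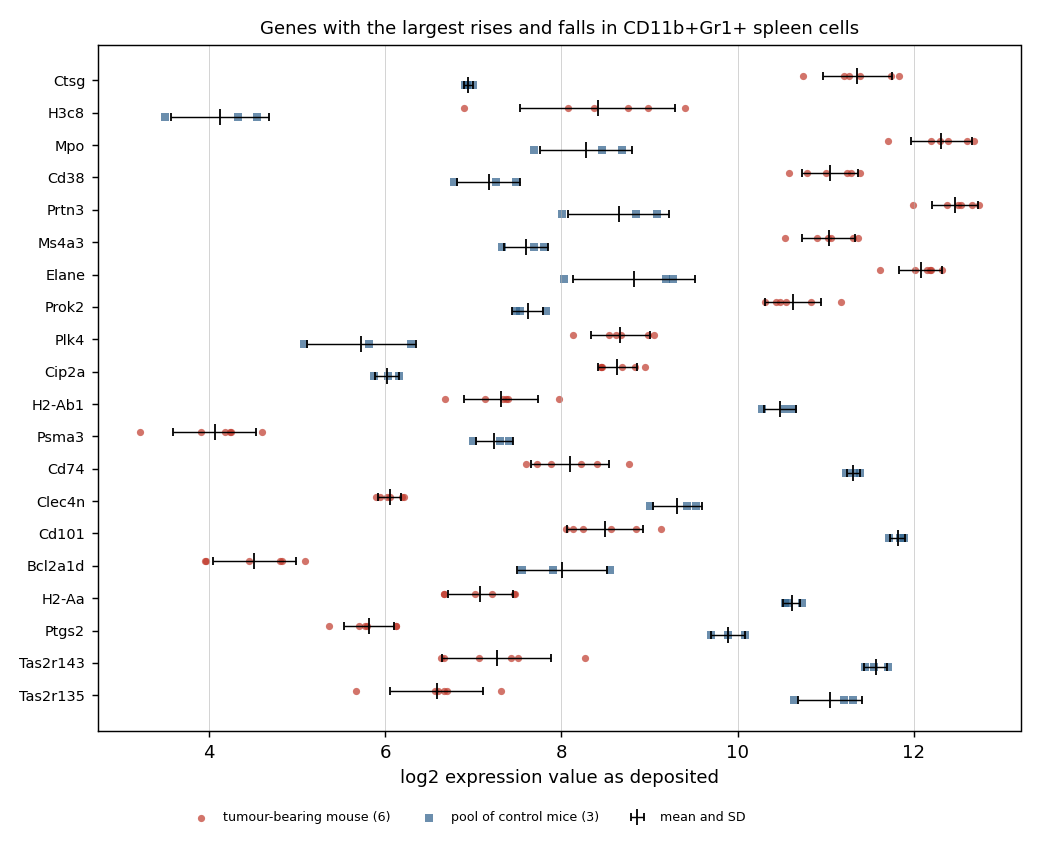
Log2 expression values (horizontal axis) of the 10 named genes with the highest rise and the 10 with the largest fall, with 1 circle per tumour-bearing mouse (6), 1 square per control pool (3), and the group mean with its SD in black. The groups do not overlap for any of the 20 genes, with Ctsg at 11.36 against 6.95 and Tas2r135 at 6.59 against 11.05.

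Named genes of cell division rose together. Of 40 mitosis genes 37 were named, and all 37 rose, by 1.13 to 2.48 on the log2 scale. They included the checkpoint kinase gene Bub1 (2.48 ± 0.16 SE), the kinetochore motor gene Cenpe (2.47 ± 0.13), Prc1 of the central spindle (2.45 ± 0.11) and the chromokinesin gene Kif4 (2.43 ± 0.13). Of 34 DNA replication genes 23 were named and all rose, among them Rfc4 of the clamp loader (2.48 ± 0.13), the ribonucleotide reductase gene Rrm1 (2.36 ± 0.15), the helicase gene Mcm6 (2.00 ± 0.20) and the polymerase gene Pole (1.92 ± 0.16). The list tests gave camera adjusted p = 1.72e-07 for mitosis and 0.000379 for DNA replication; these became adjusted p = 0.36 and 0.407 with an estimated correlation. Myb, a transcription factor of proliferating progenitors and the only named member of the stem and progenitor cell markers, rose by 1.61 ± 0.14.

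The named granule genes rose and the named mature neutrophil genes fell. Of 12 primary granule genes 6 were named and all 6 rose, by 1.64 to 4.42 (camera adjusted p = 0.0168; adjusted p = 0.36 with an estimated correlation). The direction test did not pass for this list (adjusted p = 0.0544). Of 19 secondary granule genes the ficolin gene Fcnb (1.90 ± 0.14) and the granulocyte transcription factor gene Cebpe (1.20 ± 0.07) were named, and both rose. Of 28 mature neutrophil genes 5 were named and all fell (camera adjusted p = 0.0265; adjusted p = 0.36 with an estimated correlation). They included the interleukin-1 beta gene Il1b (-2.51 ± 0.31), the lectin gene Clec4d (-2.13 ± 0.25), Rsad2 (-1.74 ± 0.17) and the chemokine gene Ccl6 (-1.36 ± 0.09). Il1b still had a mean of 10.56 ± 0.55 (SD, n = 6) in the tumour-bearing mice, against 13.08 ± 0.19 (SD, n = 3).

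Of 27 mediators through which myeloid cells restrain T cells 7 were named. Nos2, which makes nitric oxide, rose by 1.52 ± 0.16, while 6 fell, among them Ptgs2, Cd274 (the ligand PD-L1, -3.15 ± 0.12), the receptor gene Cd244a (-1.88 ± 0.14) and the cystine transporter gene Slc7a11 (-1.79 ± 0.11). Camera gave an adjusted p of 0.0265 for this list (adjusted p = 0.36 with an estimated correlation), and the direction test did not pass (adjusted p = 0.0759). Named monocyte and macrophage markers (mean difference -1.55, 10 of 10 lower) and immediate-early and heat-shock genes (-1.40, 8 of 8 lower) moved in the same direction as the 6 that fell. The proton channel gene Hvcn1, the only named gene of 9 on the NADPH oxidase list, rose by 1.08 ± 0.07.

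The named inflammatory and interferon genes fell. The 5 named genes of 24 inflammatory cytokines and chemokines fell, with Il1b, Csf1 (-2.23 ± 0.12), Il1rn (-1.23 ± 0.12) and Il18 (-1.19 ± 0.15), at camera adjusted p = 0.0265 (adjusted p = 0.36 with an estimated correlation). Of 16 NF-kappaB targets 2 were named and both fell, Tnfaip3 by 1.17 and Icam1 by 1.13 on the log2 scale. Of 30 type I interferon response genes 10 were named and all fell, led by Ifi44 (-3.03 ± 0.25), Oasl2 (-2.45 ± 0.26) and the deISGylase gene Usp18 (-1.91 ± 0.24). Of 21 interferon-gamma response genes 10 were named and all fell, led by the guanylate-binding protein genes Gbp2 (-1.92 ± 0.18), Gbp5 (-1.77 ± 0.10) and Gbp3 (-1.67 ± 0.10) and the GTPase gene Irgm1 (-1.56 ± 0.14). Both interferon lists had camera adjusted p = 0.00338 (adjusted p = 0.36 with an estimated correlation).

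The named MHC class II genes and the named monocyte, macrophage and dendritic cell markers were lower. Of 13 MHC class II genes 5 were named and all fell, including the transactivator gene Ciita (-1.94 ± 0.15), at camera adjusted p = 0.0152 (adjusted p = 0.36 with an estimated correlation). Of 28 monocyte and macrophage markers 10 were named and all fell, among them Adgre1 (F4/80, -2.01 ± 0.15), Csf1r (-1.95 ± 0.13), Nr4a1 (-1.90 ± 0.11) and Mpeg1 (-1.78 ± 0.10), at camera adjusted p = 0.00338 (adjusted p = 0.36 with an estimated correlation). Of 17 dendritic cell markers 2 were named, Itgax (-2.96 ± 0.13) and Cd209a (-2.37 ± 0.28), and both fell. Cd22 (-2.20 ± 0.11), the only named gene of 23 B cell and plasma cell markers, fell. Thbs1, the only named gene of 18 platelet markers and of 29 fibroblast-acting factors, fell by 1.21 on the log2 scale. The only named gene of 14 basophil and mast cell markers, Ms4a2 (1.46 ± 0.15), rose. So did the transferrin receptor gene Tfrc (1.21 ± 0.23), the only named gene of 30 erythroid markers. So few named markers do not show a shift of these cell types. Cd209a, Il18 and Thbs1 did not pass with a separate variance for each group.

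Of 26 immediate-early and heat-shock genes, which respond to stimulation and to handling of cells, 8 were named and all 8 fell, including Ier5 (-1.78 ± 0.12), Fos (-1.58 ± 0.13) and Junb (-1.40 ± 0.11). Camera gave adjusted p = 0.00641 (adjusted p = 0.36 with an estimated correlation). The mean of these genes was 9.28 ± 0.04 (SD, n = 6) in the tumour-bearing mice and 10.68 ± 0.21 (SD, n = 3) in the control pools. These falls accompanied those among the named genes of the cytokine, interferon, MHC class II, suppressive mediator, mature neutrophil and monocyte lists. Fos, Junb and Ier5 did not pass with a separate variance for each group, nor did Fas of the survival list.

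The remaining lists were mixed or held few named genes. The amino-acid response genes Slc7a5 (1.50 ± 0.15) and Asns (1.36 ± 0.07) rose while Ddit3 (-1.48 ± 0.10) fell, with a camera adjusted p of 0.72 for the endoplasmic reticulum stress list. Of the heme, iron and oxidative stress genes Gclm (1.56 ± 0.07), Nqo1 (1.47 ± 0.19) and Tfrc rose and Slc7a11 fell (camera adjusted p = 0.58). Of 20 cholesterol synthesis genes 3 were named, Nsdhl (1.56 ± 0.20), Hsd17b7 (1.13 ± 0.09) and Sqle (1.12 ± 0.15), and all rose (camera adjusted p = 0.193). Of 24 genes on the colony-stimulating factor list 2 were named, the receptor genes Csf1r and Csf3r (-1.01 ± 0.10), and both fell. Of 6 named granulocyte and monocyte transcription factors 3 rose and 3 fell, the latter being Nr4a1, Zeb2 (-1.58 ± 0.12) and Rara (-1.27 ± 0.13), at camera adjusted p = 0.767. Of 23 survival and apoptosis genes 5 were named. The death receptor gene Tnfrsf10b rose (1.12 ± 0.08) and 4 fell, including Fas (-1.50 ± 0.16) and Pmaip1 (-1.31 ± 0.14), at camera adjusted p = 0.171. The 8 lists with 0 named genes were alarmins and S100 genes, glycolysis and hypoxia, T cell, natural killer cell, eosinophil and squamous epithelial markers, ribosomal proteins and sex-linked genes, and they were not analysed here.

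Of the 16 lists tested, 11 passed camera with the preset correlation and 0 with an estimated correlation, where 0 also had an unadjusted p under 0.05 (the smallest was 0.0714). Random sets of falling named genes were correlated above the preset, so the p values at the preset are likely too small. Fry passed all 16, and the direction test passed 9. Fry asks whether the genes of a list move in a shared direction, without comparing them with other genes. The authors had selected every named gene for change. Passing fry was therefore close to fixed in advance for lists whose named genes all went the same way, though not by selection alone for mixed lists. In each list the count of genes past the threshold was the same adjusted over the list alone as over all rows, because the authors chose the named genes on these samples; neither count is independent evidence.

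**Figure D2:**
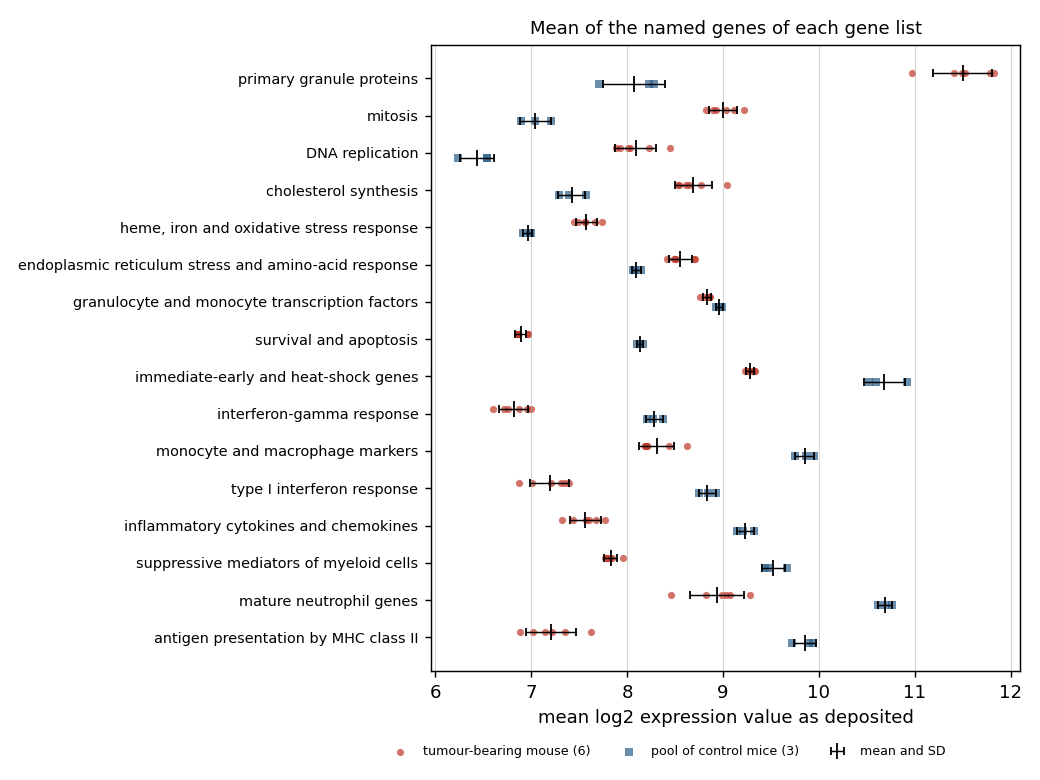
Mean log2 expression value (horizontal axis) of the named genes of each of the 16 lists tested, with 1 circle per tumour-bearing mouse (6), 1 square per control pool (3), and the group mean with its SD in black. Primary granule genes had means of 11.50 against 8.07 and MHC class II genes of 7.21 against 9.85 in tumour-bearing mice against controls.

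The authors' deposited table holds 513 rows that were higher and 451 that were lower in tumour-bearing mice, and limma gave all 964 the same direction with an adjusted p of at most 0.00587. All 964 separated the 2 groups completely, as did 7858 of all rows (24.8%, where chance gives 2.38%). The direction could not differ, because both are the difference of the same group means. The authors chose the 964 rows on these samples, so their low p and complete separation are not independent evidence. The methods' t-test at the authors' thresholds passed 969 rows, 505 higher and 464 lower, of which 953 are in the authors' table. The other 11 rows of that table had p up to 0.00217. At the same thresholds limma passed 1033 rows, including all 964, and 69 that the authors' table does not list, 15 higher and 54 lower.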

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

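Cebpe, the granulocyte transcription factor gene, had 1 tumour-bearing mouse apart from the rest. Mouse 3 stood at 11.34 while the other 5 lay between 11.13 and 11.20, a gap of 0.649 of the group's range. Of 96 items examined in this way 1 stood out, where chance gives about 4.8, and all 6 mice remained above the 3 control pools.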

How the results depend on the processing

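Limma at the authors' thresholds and the direction test were chosen after seeing the data. The count of 7333 changed rows fell to 3800 with a Welch test, which estimates a separate spread from the 3 pools, and to 895 when only named rows were tested, because fewer rows entered. With the replicate block, which keeps 3 mice and 3 pools, it was 4289. Same-numbered samples had deviation correlations of 0.09, 0.01 and 0.02, so the numbers were not read as pairs. The block ended the calls of Pmaip1, Thbs1 and Usp18. The other 8 alternatives gave 6606 to 7584 rows. Leaving out 1 sample gave 6201 to 7113 changed rows, 481 to 611 higher and 541 to 606 lower by at least 2-fold, 11 lists shifted in every case and all 964 of the authors' rows called. Of these rows 810 passed with a Welch test, 892 with the block and 898 with the filter on dim rows, which removes some. Rows higher by at least 2-fold numbered 442 to 605 and rows lower 408 to 622 over the other alternatives. Camera with an estimated correlation passed 0 lists. Deviations from the group means had a median correlation of 0.2 in random sets of falling named genes, above the preset 0.01. The p values at the preset are therefore likely too small. No further test of the cause was made. The direction test ended the calls of the primary granule and suppressive mediator lists (adjusted p = 0.0544 and 0.0759). Fry, which asks for a shared direction without comparison with other genes and was run on genes selected for change, added 5. For the 80 named genes, 1584 of 1596 values under alternatives kept direction and call, 12 lost the call (9 with a Welch test, 3 with the block; highest adjusted p 0.15) and 0 reversed. Under each of the other alternatives 11 lists passed, including with cameraPR on the methods', Welch and trended statistics. Background signal was not used here, so dim rows were not separated from undetected ones.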

Other observations

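The gene families, the tests of scaling, of single mice, of adjacent pairs of genes and of other splits, and the comparison of list correlations with random pairs of gene sets were chosen after the data had been seen. The families were assembled with directions in view from genes the authors had selected for change, so their counts describe the named genes and are not a test. All 11 named kinesin genes were higher, by 1.61 to 2.43 (log2), and 4 of them are on the mitosis list, as are 3 of the 13 centromere protein genes, which were all higher too. Families outside the fixed lists were higher as well. They were 8 condensin and SMC genes, led by Ncapg (2.35 ± 0.13 SE), 13 histone genes, led by H3c8 and the linker histone gene H1f5 (2.46 ± 0.21), 5 nuclear pore genes, and 13 genes of the Fanconi anaemia and homologous recombination pathways, with Bard1 at 2.50 ± 0.17 and Fancd2 at 2.10 ± 0.17. The 5 E2F and Myb family genes, 1 of them on a fixed list, were higher.

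Other families had named genes that were lower. They included 9 pattern-recognition receptor genes, among them Nlrp3 (-2.73 ± 0.16 SE), Nod2 (-1.48 ± 0.10) and Tlr9 (-1.37 ± 0.14), and 6 C-type lectin-like receptor genes, with Clec7a, the beta-glucan receptor gene, at -2.60 ± 0.18. Of these, 2 and 1 are on fixed lists. The 5 CD300 genes, with Cd300c at -1.83 ± 0.08, and the 5 genes of the interferon-inducible p200 family, with Ifi205 at -2.75 ± 0.13, are on none of the lists and were lower. The 5 guanylate-binding protein genes, 4 of them on the interferon-gamma list, 4 Trim30 genes and 4 dual-specificity phosphatase genes were lower, while the Schlafen and Ms4a families went both ways.

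The real grouping gave far more changed rows than any other split of the samples. In 84 splits of the 9 samples into 6 and 3, only 1, the real one, gave as many changed rows (7333, where the highest other split gave 1), as many rows higher by 2-fold (561 against 1) or as many lower (560 against 0). A share of 1 in 84 is the smallest that these splits can give, so chance assignment is unlikely but not excluded. Every other split mixes the real groups, which raises the spread within its groups and keeps its counts low.

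The named monocyte and MHC class II genes fell together. Array medians lay within 5.92 to 5.99 before quantile normalization, so little scaling was left for it to remove. The mean difference of these 15 genes was -1.94 ± 0.20 (SE over genes, which vary together) after it and -1.91 as deposited. This argues only against array scaling left in the deposited values. Those values had already been normalized across arrays, so an effect of the authors' own normalization was not tested. A lower share of monocytes and dendritic cells among the sorted cells is a candidate explanation for which the CD11b+Gr1+ gate admits monocytes, whereas it works against dendritic cells, most of which carry little Gr1. Across the 6 tumour-bearing mice the 2 list means had Pearson r = 0.89 (exact permutation p = 0.0236, adjusted 0.0403 over 2 relations) and Spearman rho = 0.66 (exact permutation p = 0.175), but r became -0.29 without mice 4 and 6, so the relation rests on those mice. Random pairs of sets of falling genes had a median r of 0.72 and 86.6% lay below 0.89. These sets were drawn from all falling named genes, these lists included, which the same cause could move, so the comparison cannot decide. A lower share cannot be told apart from lower expression per cell.

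The named cell-cycle and primary granule genes rose together. Array medians lay within 5.92 to 5.99 before quantile normalization, so little scaling was left for it to remove. The mean difference after it was 1.93 ± 0.08 (SE over 66 genes, which vary together). This argues only against array scaling left in the deposited values. An effect of the authors' own normalization was not tested. The means of these genes in each mouse were 8.69 to 9.18, the lowest of which lay 1.62 above the highest pool (pools 6.74 to 7.07, SD 0.18 among mice and 0.17 among pools). The rise of these genes was thus present in all 6 mice. All 964 of the authors' rows separated the groups completely, so no other order of the means was possible. It is therefore no test of a single mouse as the cause. A larger share of dividing granulocyte precursors is a candidate explanation. Across the 6 mice the mitosis and primary granule means had r = 0.84 (exact permutation p = 0.0403, adjusted 0.0403 over 2 relations), rho = 0.77 (exact permutation p = 0.103) and r = 0.67 without mice 1 and 6. Only 12.6% of random pairs of sets of rising genes had a lower r (median 0.94). These sets were drawn from all rising named genes, these lists and other cell-cycle genes included, which the same cause could move. The comparison therefore cannot decide whether the correlation is specific to these lists. A larger share cannot be told apart from a change within the cells or from the tumour, genotype and pooling that coincide with group.

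Named genes that neighbour each other on a chromosome shared a direction more often than shuffled directions did. In the RefSeq order the clone 2010310C07Rik (-4.16 ± 0.32 SE), Tas2r143, Tas2r135 and Tas2r126 (-3.04 ± 0.13) follow each other with 0 genes between them; the first and last were chosen after their values were seen. Array medians lay within 5.92 to 5.99 before quantile normalization, so little scaling was left for it to remove. The mean difference of these 4 genes after it was -4.01, which argues only against array scaling left in the deposited values. Their deviations from the group means correlated at 0.77, above 99.9% of 10000 random sets of 4 falling genes. Such a correlation would arise if 1 RNA covered them, which remains a hypothesis. The random sets were not matched for spread. Tas2r135 and Tas2r143 had SDs of 0.53 and 0.61 among the mice, against a median of 0.107 over all rows. The percentile may therefore partly follow from their spread. Of 61 adjacent pairs of named protein-coding genes 83.6% shared a direction (median of shuffled directions 50.8%, permutation p = 1e-05, the smallest that 100000 permutations can give). Families of similar genes were argued against as the whole cause, since 76.7% of 43 pairs without a shared start of the symbol did so (permutation p = 0.00048), as did 73.7% of the 38 pairs left without 5 further related ones (permutation p = 0.00406); shared promoters and transcripts that run across genes were not tested.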
